A study of Danio rerio with 21 samples.

How the data were processed

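Libraries were made from polyadenylated RNA, per the labels' protocols. Zebrafish libraries came from pools of 30 embryos and a NEBNext Ultra kit. Embryos had been injected with 2 nl holding 8 ng of control morpholino, or 4 ng each of morpholinos against rbm14a and rbm14b, with 100 pg of GFP mRNA. Mouse libraries were made by Geo-seq, a PCR amplification of single embryos, and a Nextera XT kit from blastocysts of a cross between Rbm14 heterozygotes cultured in KSOM medium. Reads were aligned with HISAT2 2.1.0 and counted with featureCounts 1.5.3 on GRCz10 and GRCm38, per the submitters' processing notes. The authors deposited the values of each species in TPM, scaled by gene length and library total so that each library sums to 1000000, with no annotation release or strand setting stated. Zebrafish titles call the knockdown by the number 14, read here as rbm14a and rbm14b from the treatment protocol. The zebrafish data hold 31624 gene identifiers, of which 26154 (82.7%) were given a symbol from a gene name list without coordinates. The mouse data hold 23420 symbols and no mitochondrial genes. Symbols shared by several identifiers were tested per identifier.

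TPM values of a gene are whole fragments times a scale per library and gene, so whole fragment numbers were recovered from exact ratios between libraries (tolerance 1e-08) for 27259 zebrafish and 19079 mouse genes. They give the depth per library, the floors (3 fragments), the chi-square between replicates and the counts for limma-voom, and entered nothing else. Where genes were above 0 in 1 library only (1387 in zebrafish, 2416 in mouse), 1 fragment was assumed. The smallest whole numbers that fit were taken, so fragment numbers can be too low where all libraries share a factor.

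The samples, gene lists, naming rule and main tests were fixed before the data were examined, and so were the alternatives except those said to be chosen after. Genes with at least 1 TPM in at least 2 zebrafish libraries (17920) or 3 mouse libraries (11781) were tested with limma-trend on log2(TPM + 1). The model had 6 group means in zebrafish (6 residual and 4.30 prior degrees of freedom) and 2 in mouse (7 and 5.4), with Benjamini-Hochberg adjustment within a contrast and a threshold of 0.05. A second count asked for a log2 change of at least 1. In each species 22 gene lists were tested, where at least 5 members were measured, with camera (preset correlation 0.01), with camera at an estimated correlation, and with fry. Camera compares a list with all other genes, and fry asks whether its members move one way. Temporal classes were taken from the mean change between 2.5 and 6 hpf over both injections, which in this balanced design is independent of the morpholino difference. Classes and mouse list means were compared with exact permutation tests over all arrangements of libraries within times and all 84 splits of embryos. The control hour matched was read from straight lines between control times.

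Genes named were drawn from the targets, the 8 largest rises and falls past the threshold with at least 5 TPM in the higher group, no overlap between the groups and a gene symbol (5 for the average and the interaction). To these come up to 4 members with the smallest p of each list called or discussed (3 in the control time course). In mouse, where none passed, they are the 5 smallest p each way. Some genes this rule selects are not reported here. Lists discussed without a camera call, and the genes drawn over time, were picked after their values were seen.

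The main steps were tested on simulated data drawn from each gene's mean over all groups and its fitted spread. Few genes were changed and noise was independent between genes. In the data far more genes differed, so the shares recovered and the false calls need not carry over. For the comparisons at 2.5, 4 and 6 hpf (16784 genes), limma recovered 28.4%, 50.7% and 37.3% of genes changed 1.5-fold and 91%, 82.1% and 92.5% of those changed 2-fold. Of those changed 4-fold it recovered 100%, 100% and 97%, with 2 of 164, 11 of 182 and 7 of 173 calls false. For mouse (11407 genes) it recovered 0%, 0% and 9.09%, with 1 of 8 calls false. A simulated delay to 3.25 and 4.5 hpf was read back as 3.25 and 4.5 hpf in declining and 3.24 and 4.5 hpf in rising genes. It was built and read with the same straight lines and a set noise, so it checks the calculation only. Alternatives tried were the pseudocount, the filter, median-of-ratios rescaling, quantile normalization, limma arrayWeights, robust eBayes, a replicate block, the compared libraries alone, each library left out, other class thresholds, and limma-voom. Work was done in R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the main tests.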

Results

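Polyadenylated RNA was measured in zebrafish embryos injected against rbm14 and in mouse blastocysts labelled Rbm14 ko, each with controls. Rbm14 is an RNA-binding protein of nuclear and cytoplasmic condensates. The fish part held 12 libraries in 6 groups of 2, each from a pool of 30 embryos. Embryos were injected with a control morpholino or with morpholinos against rbm14a and rbm14b and collected at 2.5, 4 or 6 hours post fertilisation (hpf). These times span the last cleavages on maternal RNA, the start of zygotic transcription and early gastrulation. The mouse part held 9 single embryos at embryonic day 4.5, 3 labelled control (2, 5 and 10) and 6 labelled ko (3, 4, 6, 7, 8 and 9). Fish libraries held 18300210 to 24374174 fragments with 13594 to 15567 genes at 1 TPM or more. Their replicates correlated at r = 0.994 to 0.996 across all genes and at 0.99 to 0.994 across the genes tested. Mouse libraries held 12183631 to 14403449 fragments in 5 embryos and 9983248 in control 10. The shallowest were ko 9 (9213391), ko 8 (5972201) and control 5 (3720585), where 5810 genes reached 1 TPM. The other embryos had 9147 to 11546 genes at that level. The labels do not say whether replicate pools came from separate clutches, so p-values measure the spread between these samples. Detection floors cover counting error only, since PCR reads carry no molecular identifiers. Because polyadenylated RNA was measured, a change in poly(A) tails cannot be told apart from a change in RNA amount. Changes are on the log2 scale with limma's standard error after the ± sign. TPM values are means with the SD over 2 libraries, and all tests are two-sided.

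RNA levels of the targeted genes were looked at as a check of the labels, which they did not settle. In controls rbm14a (ENSDARG00000012723) stood at 52.0 and 68.9 TPM at 2.5 hpf, 113 and 108 TPM at 4 hpf and 83.9 and 86.1 TPM at 6 hpf. In morphants it stood at 48.4 and 61.0, 100.5 and 97.6, and 117 and 112 TPM at the same times. The other target, rbm14b (ENSDARG00000103834), stood at 23.9 and 31.9, 42.4 and 37.7, and 43.6 and 36.0 TPM in controls. In morphants it stood at 34.3 and 39.2, 48.8 and 44.6, and 74.5 and 69.7 TPM. At 6 hpf rbm14b rose by 0.85 ± 0.15 (limma adjusted p = 0.000315), but by 0.15 after median-of-ratios rescaling (adjusted p = 0.342). The rise of rbm14a at 6 hpf, 0.43 ± 0.14 (limma adjusted p = 0.0132), turned to -0.27 after rescaling, and its call ended without replicate 1 of either group. RNA levels do not show how far the proteins were reduced, because a morpholino can act without lowering its target's RNA. In mouse, Rbm14 stood at 189 TPM in control 2, 62.7 in control 5 and 36.6 in control 10. It stood at 38.9, 35.9, 29.0, 27.1, 43.3 and 56.7 in the 6 ko embryos in the order given above. The ko embryos thus still carried Rbm14 RNA, and the library labelled control 10 lay within their range. Rbm14 averaged 38.5 ± 10.8 TPM in ko and 96.1 ± 81.5 TPM in control embryos (SD, n = 6 and 3; limma adjusted p = 0.761, and exact permutation p = 0.0595).

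Control embryos give the course that morphants are set against. Between 2.5 and 4 hpf, 44 of 47 early zygotic genes rose and 1 fell, led by the SOXB1 factor sox19a (6.81 ± 0.09), nnr (8.12 ± 0.13) and asb11 (8.02 ± 0.14). Of 33 oocyte and egg genes 19 fell and 4 rose in the same interval (camera adjusted p = 2.91e-05, and adjusted p = 0.266 with an estimated correlation). Among the falls were slbp2, an oocyte histone mRNA-binding protein (-1.98 ± 0.10), and the mitotic cyclin CCNB1 (-1.05 ± 0.06). Of 16 germ plasm genes 12 fell, such as TDRD6 (-2.60 ± 0.17), and 2 rose (camera adjusted p = 0.000121, and adjusted p = 0.0871 with an estimated correlation). Between 4 and 6 hpf all 81 ribosomal protein genes rose, with RPLP0 going from 187 to 1387 TPM. Mesendoderm genes rose too, 26 of 28, among them the segmentation factor mespab (7.25 ± 0.17). So did 23 of 28 enveloping layer genes, such as ANXA1 (5.80 ± 0.14). In that interval 26 of 33 oocyte and egg genes fell, cldnd by 4.46 ± 0.11 and the maternal pluripotency factor nanog from 2979 to 136 TPM. Of 17920 genes tested, limma called 8601 between 2.5 and 4 hpf (4824 up, 3777 down; 4021 up and 5274 down with quantile normalization) and 14547 between 4 and 6 hpf (4980 up, 9567 down). The median of all genes moved by -0.55 in the second interval. After rescaling, 14224 genes split into 7662 up and 6562 down. Camera called 13 lists in the first interval and 17 in the second, of which 1 (early zygotic genes, adjusted p = 0.0428) and 5 held with an estimated correlation.

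At 2.5 hpf, the question was whether embryos injected against rbm14 already differ while they still run on maternal RNA. ITM2C, a transmembrane protein gene, stood at 284 ± 4.41 TPM in morphants and 78.2 ± 4.04 TPM in controls (1.85 ± 0.10; limma adjusted p = 5.37e-06). CPOX, an enzyme of haem synthesis, stood at 209.8 ± 8.64 TPM in morphants and 67.6 ± 2.29 TPM in controls (1.62 ± 0.10). Other large rises were those of alox5b.3 (1.82 ± 0.20), the membrane scaffold FLOT1 (1.63 ± 0.20) and the protein kinase A subunit prkacbb (1.48 ± 0.26). So were those of the ubiquitin ligase UBR2 (1.44 ± 0.28), the germ cell RNA-binding protein DAZL (1.43 ± 0.23) and the histone chaperone RBBP4 (1.35 ± 0.08). The iron-storage gene fthl27 fell by 3.03 ± 0.11, from 487 ± 63.8 to 58.8 ± 9.27 TPM, and its relatives fthl28 (-2.77 ± 0.43) and fthl31 (-2.42 ± 0.17) fell too. Reads could be split between these similar ferritin genes. The deubiquitinase CYLD (-2.58 ± 0.17), the ephrin receptor ephb4b (-2.24 ± 0.18), the checkpoint gene rad9a (-2.22 ± 0.22), cdcp1a (-2.22 ± 0.14) and the RNA helicase DDX27 (-2.20 ± 0.09) fell as well.

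All 13 protein-coding genes of the mitochondrial genome rose at 2.5 hpf (median 0.65; camera adjusted p = 1.16e-15, and adjusted p = 0.375 with an estimated correlation), MT-CO1 from 5632 ± 266 to 9039 ± 599.5 TPM. Of 94 nuclear genes of oxidative phosphorylation, 37 fell and 8 rose (8 up and 43 down adjusted over the list alone), among them the ATP synthase subunit ATP5F1B (-1.24 ± 0.10) and the cytochrome gene CYC1 (-0.80 ± 0.08). Their camera call (adjusted p = 0.0199, and adjusted p = 0.987 with an estimated correlation) ended without control 2.5 hpf replicate 1 (adjusted p = 0.258), without morphant 2.5 hpf replicate 2 (0.986) and after rescaling (0.0639). Ribosomal protein genes had 18 rises and 5 falls among 81 (19 up and 5 down adjusted over the list alone) with a median of 0.21 (camera adjusted p = 1.23e-10, and adjusted p = 0.984 with an estimated correlation). Their members with the smallest p, such as RPL4 (-0.87 ± 0.09) and the biogenesis factor RPL7L1 (-1.42 ± 0.12), fell. Deadenylation and decay factors, a list whose camera test did not pass (adjusted p = 0.886), had 17 falls and 6 rises among 56 (6 up and 17 down adjusted over the list alone). Among the falls were the CCR4-NOT subunits CNOT10 (-1.44 ± 0.11), CNOT4 (-1.34 ± 0.12) and CNOT3 (-1.16 ± 0.14) and the deadenylase parn (-0.78 ± 0.07). Early zygotic genes had 1 rise (blf, 0.58 ± 0.13) and 2 falls. The lists of oocyte genes (adjusted p = 0.0148), paraspeckle proteins (adjusted p = 0.0148) and mitotic genes (adjusted p = 0.0294) were also called upward with the preset correlation. With an estimated correlation their adjusted p were 0.984, 0.955 and 0.955. Camera's direction is relative to other genes: the mitotic median was 0.033 and that of all genes -0.13. The oocyte call ended without morphant replicate 1 (adjusted p = 0.482) and the paraspeckle call without control replicate 1 (0.258) or morphant replicate 2 (0.062). The mitotic call ended without control replicate 2 (0.11) or morphant replicate 2 (0.239). Limma called 4430 of 17920 genes (768 up, 3662 down), 691 of them with a change of 1 or more, and the median of all genes moved by -0.13. After median-of-ratios rescaling 3876 genes split into 1912 up and 1964 down. Fragments of replicates differed more at 2.5 hpf (chi-square per gene 36.54 in morphants and 12.24 in controls) than at later times (3.18 to 6.01). The spread that limma shares between groups may therefore be too small here. Limma arrayWeights called 2830 genes, and only the 4 libraries compared gave 2070 of 14113. Without control 2.5 hpf replicate 1 or 2 the count was 2924 or 2842.

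At 4 hpf the comparison asks whether zygotic genes come on in morphants as in controls. They were lower: of 47 early zygotic genes 33 fell and 3 rose (median -1.27; 3 up and 34 down adjusted over the list alone; camera adjusted p = 2.86e-14, and adjusted p = 0.115 with an estimated correlation). The T-box factor tbx16 stood at 17.4 ± 4.17 TPM in morphants and 149.7 ± 21.2 TPM in controls (-3.05 ± 0.16; limma adjusted p = 2.21e-06). The small heat shock gene HSPB1 stood at 90.4 ± 12.8 TPM in morphants and 576 ± 113 TPM in controls (-2.65 ± 0.13). The RNA polymerase III subunit gene polr3gla (-2.51 ± 0.16) and the yolk syncytial homeobox gene mxtx1 (-2.69 ± 0.18) followed. Enveloping layer genes had 16 falls and 4 rises among 28 (camera adjusted p = 1.02e-05, and adjusted p = 0.169 with an estimated correlation). The keratin genes krt4 (-3.45 ± 0.20), krt92 (-3.61 ± 0.27), krt18a.1 (-2.91 ± 0.21) and krt8 (-2.01 ± 0.12) fell, a family in which reads could be split. Yolk syncytial layer genes had 14 falls and no rise among 25 (adjusted p = 3.41e-06, and adjusted p = 0.115 with an estimated correlation), such as the lipoprotein gene apoeb (-1.47 ± 0.13). Other large falls were those of CDK5R1, an activator of CDK5 (-3.94 ± 0.26), the retinoic acid carrier CRABP2 (-3.70 ± 0.14) and the TEAD cofactor vgll4l (-3.61 ± 0.25). They were followed by stm (-3.51 ± 0.16) and the sodium pump subunit ATP1B1 (-3.24 ± 0.23).

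Axis genes were low at 4 hpf as well. Mesendoderm and Nodal genes had 17 falls and 3 rises among 28 (camera adjusted p = 7.13e-07, and adjusted p = 0.148 with an estimated correlation). Dorsal organizer genes had 11 falls and 3 rises among 20 (adjusted p = 0.00183, and adjusted p = 0.225 with an estimated correlation). The BMP antagonist chrd (-2.40 ± 0.17) and GSC (-1.67 ± 0.15) are in both lists. Ventral and BMP genes had 13 falls and 3 rises among 26 (adjusted p = 0.00151, and adjusted p = 0.249 with an estimated correlation), among them bmp7a (-2.60 ± 0.22) and vent (-1.75 ± 0.13). FGF response genes had 10 falls and 2 rises among 16 (adjusted p = 0.00077, and adjusted p = 0.249 with an estimated correlation), among them the feedback inhibitor SPRY4 (-2.03 ± 0.19). Ribosomal protein genes had 56 falls and no rise among 81 (median -0.53; 0 up and 63 down adjusted over the list alone; camera adjusted p = 5.61e-17, and adjusted p = 0.376 with an estimated correlation). Maternal genes were higher in morphants in contrast. Across the genes that decline over time, differences at 2.5 and 4 hpf correlated at r = 0.52, though genes are not independent. Part of the difference at 4 hpf was thus present earlier. Oocyte and egg genes had 17 rises and 2 falls among 33 (18 up and 3 down adjusted over the list alone; camera adjusted p = 7.8e-05, and adjusted p = 0.376 with an estimated correlation). Examples are the egg coat gene zp3b (1.43 ± 0.09), sox19b (1.29 ± 0.08) and cldnd (1.19 ± 0.11). Germ plasm genes had 10 rises and no fall among 16 (12 up and 1 down adjusted over the list alone; adjusted p = 0.000271, and adjusted p = 0.148 with an estimated correlation). DAZL (1.94 ± 0.23), already higher at 2.5 hpf, and PIWIL2 (0.74 ± 0.11) were among the rises. The largest rises were those of the RNA-binding protein raver1 (2.50 ± 0.14), the stress gene GADD45G (2.32 ± 0.23), and the poly(A) polymerase TENT4A (2.25 ± 0.21). The last stood at 282 ± 39.1 TPM in morphants and 58 ± 0.942 TPM in controls. Next came the DNA repair helicase fancm (2.21 ± 0.19), the thioredoxin reductase TXNRD3 (2.04 ± 0.07), the hyaluronidase CEMIP2 (2.03 ± 0.18), cln6a (2.01 ± 0.18) and the death ligand TNFSF10 (1.95 ± 0.25). Deadenylation factors split into 8 rises and 8 falls among 56 (camera adjusted p = 0.58), and the CCR4-NOT deadenylase CNOT7 rose by 1.93 ± 0.15. Paraspeckle and related proteins had 7 falls and 2 rises among 20 (adjusted p = 0.0379, and adjusted p = 0.479 with an estimated correlation). Their call ended without morphant 4 hpf replicate 2 (0.0541). The upward call of the mitochondrial genome list (adjusted p = 0.00795, and adjusted p = 0.479 with an estimated correlation) ended without that library (0.0541) or control 4 hpf replicate 1 (0.0708). Limma called 5755 of 17920 genes (2828 up, 2927 down), 1515 of them with a change of 1 or more. Without replicate 1 of the controls the count was 3649, and without replicate 1 of the morphants 3576.

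The comparison at 6 hpf asks whether maternal transcripts are cleared and the gastrula programme starts. Morphants still held polyadenylated oocyte transcripts that were reduced in controls. The cyclin CCNA1 stood at 2974 ± 8.2 TPM in morphants and 97.9 ± 17.6 TPM in controls (4.92 ± 0.11; limma adjusted p = 3.96e-10), and nanog at 2735 ± 198 TPM in morphants and 136 ± 16.8 TPM in controls (4.33 ± 0.11). BTG4, an adaptor that brings CCR4-NOT to maternal transcripts, stood at 167 ± 2.38 TPM in morphants and 4.38 ± 2.17 TPM in controls (5.03 ± 0.23). Oocyte and egg genes had 27 rises and 4 falls among 33 (median 2.69; 27 up and 4 down adjusted over the list alone; camera adjusted p = 5.21e-05, and adjusted p = 0.27 with an estimated correlation). All 16 germ plasm and germ cell genes rose (median 2.28; adjusted p = 5.21e-05, and adjusted p = 0.086 with an estimated correlation), such as ca15b (2.82 ± 0.10), PIWIL2 (2.67 ± 0.11) and HOOK2 (2.73 ± 0.12). The claudin genes cldng (5.28 ± 0.19) and cldnd (4.83 ± 0.11), arpp21 (5.21 ± 0.18), the cyclophilin gene ppifb (4.82 ± 0.95) and USH1G (4.81 ± 0.19) were among the largest rises, with the hairy-related repressor her5 (5.43 ± 0.12). Controls lowered her5 from 252 TPM at 4 hpf to 4.84 ± 0.555 TPM. Morphants had 142 and 151 TPM at 4 hpf and 251 ± 6.41 TPM at 6 hpf. Factors that act on poly(A) tails and decay had 32 rises and 13 falls among 56 (camera adjusted p = 0.241), although the list's median turned from 0.45 to -0.25 after rescaling. The smallest p were those of LSM14B (3.70 ± 0.12), parn (1.76 ± 0.07), the zinc finger decay factor cth1 (2.69 ± 0.11) and btg3 (2.15 ± 0.09). Reported targets of the microRNA miR-430 split into 11 rises and 9 falls among 20 (camera adjusted p = 0.878). By the temporal classes, that list mixes 8 declining with 7 rising genes. Its split therefore does not show whether maternal targets were retained.

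Genes of the gastrula programme were far lower at 6 hpf. The largest falls were those of fetub, a secreted protease inhibitor (0.803 ± 0.264 TPM in morphants and 356 ± 81.3 TPM in controls; -7.62 ± 0.21), the posterior homeobox gene eve1 (-6.73 ± 0.20) and the presomitic mesoderm factor msgn1 (-6.67 ± 0.17). They were followed by the hexokinase-like gene HKDC1 (-6.58 ± 0.17), mespab (-6.40 ± 0.17), SOX2 (-6.35 ± 0.21) and afp4 (-6.29 ± 0.18). The apolipoprotein gene apoa1b had no fragment in either morphant library against 93.7 ± 28.6 TPM in controls. That is at least 323-fold lower when 3 fragments set the floor. Mesendoderm genes had 24 falls and 3 rises among 28 (camera adjusted p = 8.97e-08, and adjusted p = 0.086 with an estimated correlation). Ventral and BMP genes had 23 falls and 1 rise among 26 (adjusted p = 3.25e-08, and adjusted p = 0.086 with an estimated correlation), with cdx4 at -6.24 ± 0.17. Dorsal organizer genes had 16 falls and 3 rises among 20 (adjusted p = 3.52e-05, and adjusted p = 0.086 with an estimated correlation), with FOXA2 at -2.69 ± 0.15. FGF response genes had 12 falls and 1 rise among 16 (adjusted p = 6.26e-05, and adjusted p = 0.147 with an estimated correlation), with DUSP6 at -2.05 ± 0.12. Enveloping layer genes had 23 falls and 2 rises among 28 (adjusted p = 2.32e-08, and adjusted p = 0.086 with an estimated correlation), for example agr1 (-5.44 ± 0.16) and anxa1c (-4.79 ± 0.14). Yolk syncytial layer genes had 21 falls and 4 rises among 25 (adjusted p = 4.97e-07, and adjusted p = 0.086 with an estimated correlation), for example the lipid transfer gene MTTP (-5.39 ± 0.18). Early zygotic genes had 33 falls and 10 rises among 47 (adjusted p = 1.08e-05, and adjusted p = 0.147 with an estimated correlation). Of 81 ribosomal protein genes 79 fell and none rose (median -1.32; camera adjusted p = 5.33e-22, and adjusted p = 0.214 with an estimated correlation), RPL18 from 1161 ± 25.4 to 343 ± 19.4 TPM.

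Paraspeckle and related proteins, the class of nuclear body proteins to which Rbm14 belongs, had 13 falls and 2 rises among 20 at 6 hpf (camera adjusted p = 5.2e-05, and adjusted p = 0.147 with an estimated correlation). EWSR1 (-2.84 ± 0.13) and TARDBP (-1.37 ± 0.07) were among the falls. Nuclear oxidative phosphorylation genes had 51 falls and 22 rises among 94 (adjusted p = 0.000259, and adjusted p = 0.553 with an estimated correlation), with NDUFV1 going up (1.87 ± 0.08). Cholesterol synthesis genes had 15 rises and 2 falls among 20, such as FDPS (2.25 ± 0.09). Their camera call (adjusted p = 0.0497, and adjusted p = 0.147 with an estimated correlation) ended without control 6 hpf replicate 1 (0.0758) or 2 (0.0991). The 13 mitochondrial genome genes rose (median 0.49; adjusted p = 0.0497, and adjusted p = 0.57 with an estimated correlation), but their median turned to -0.21 after rescaling. Their camera call ended without each of control replicates 1 (0.0565) and 2 (0.128) and morphant replicates 1 (0.0671) and 2 (0.0644). Limma called 14020 of 17920 genes (8744 up, 5276 down), 9101 of them with a change of 1 or more. The median of all genes moved by 0.40, and after rescaling 13959 genes split into 6223 up and 7736 down.

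**Figure D1:**
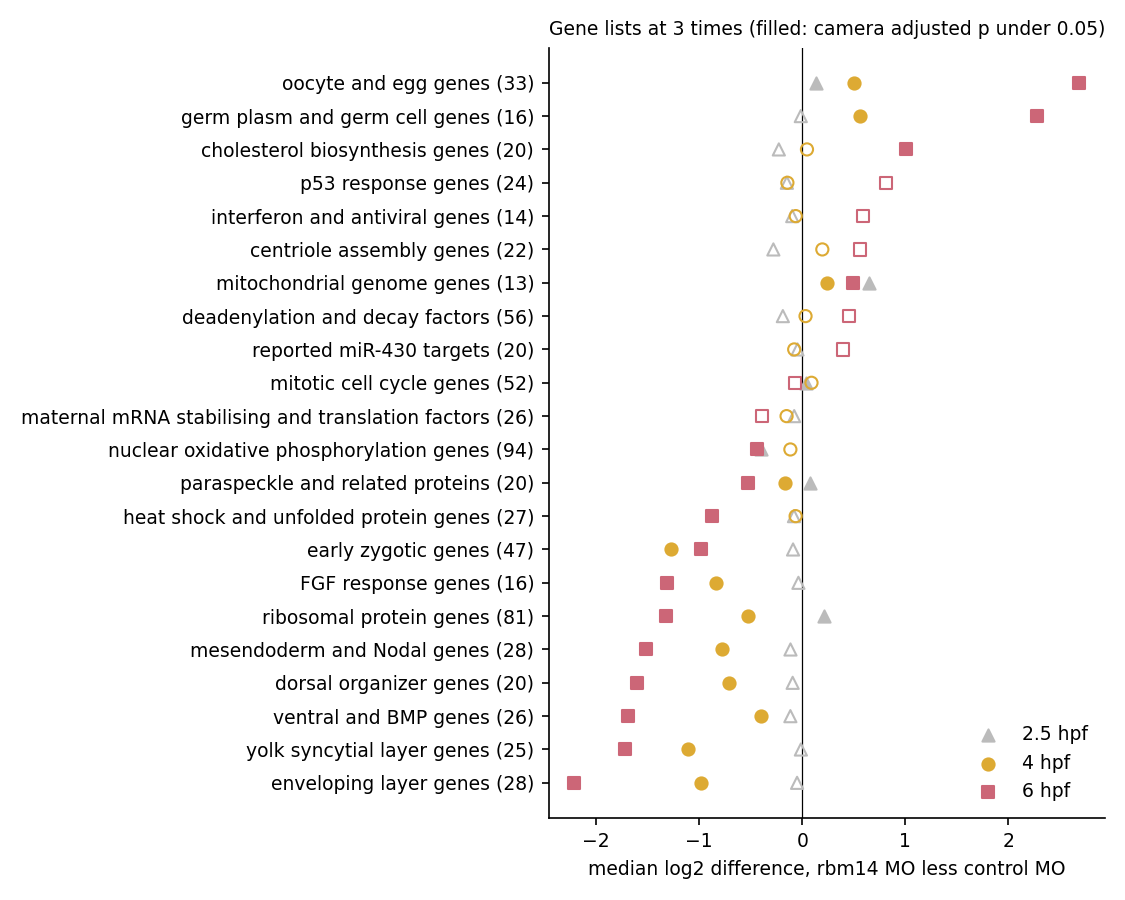
Median log2 difference (rbm14 morpholino less control morpholino) of each zebrafish gene list at 2.5, 4 and 6 hpf. Germ plasm genes reach 2.28 and enveloping layer genes -2.21 at 6 hpf.

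**Figure D2:**
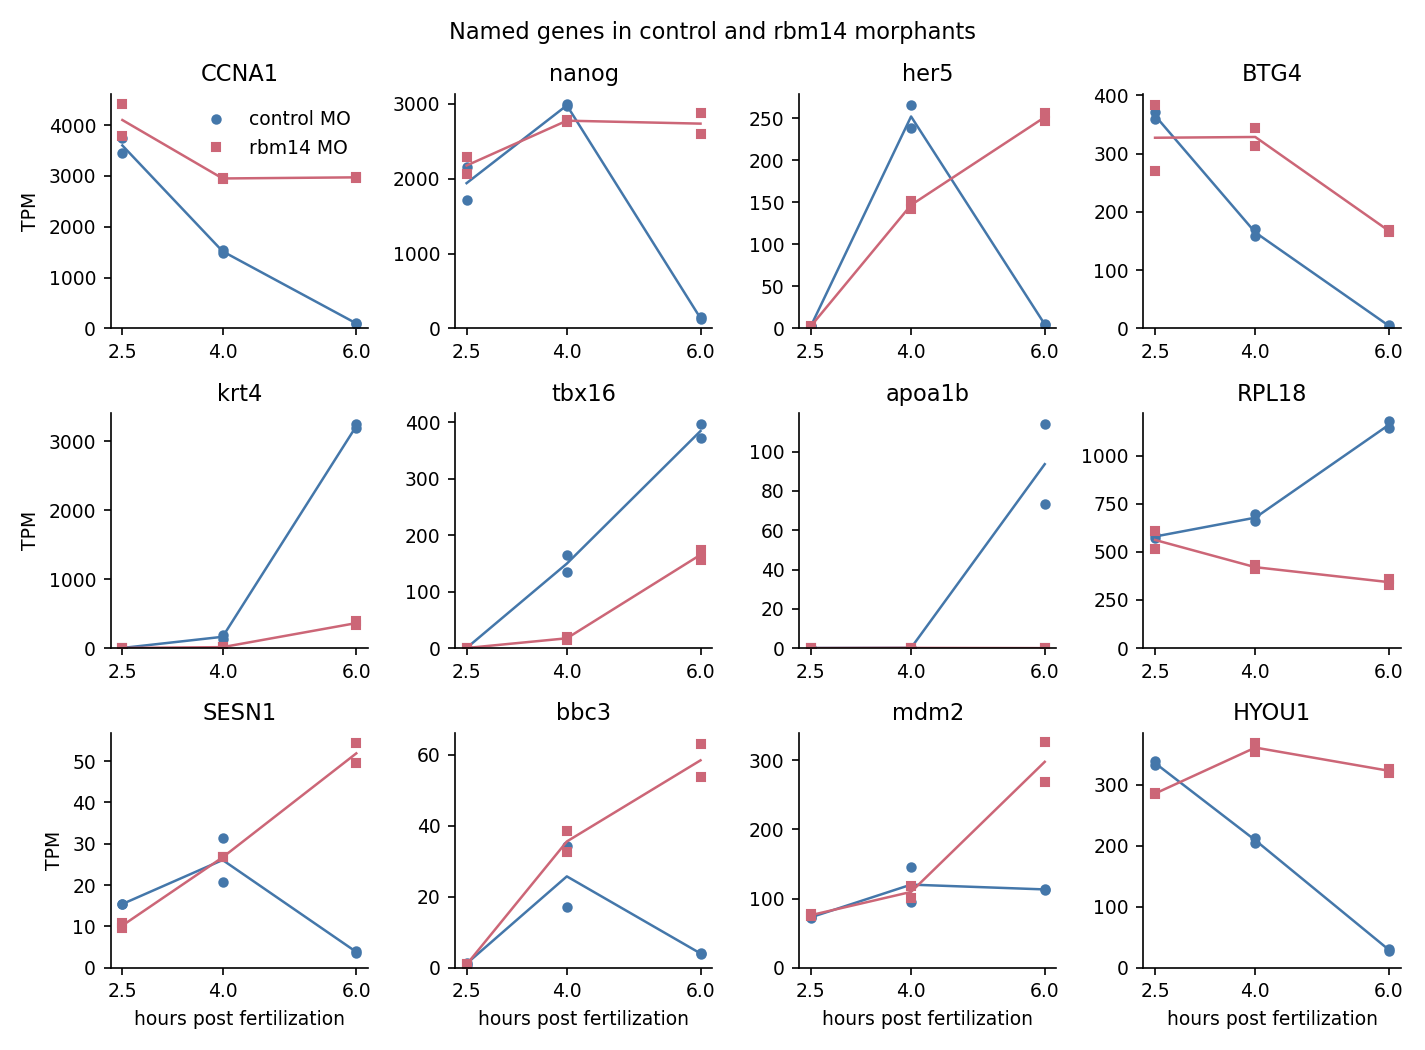
TPM of single genes in each library against hours post fertilisation for control and rbm14 morpholinos. her5 reached 251 TPM in morphants at 6 hpf, where controls had 4.84 TPM.

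The average over the 3 times and the interaction with time ask which genes differ in the mean over times and which change their course. The largest average rises were those of sumo2a (2.48 ± 0.17), a ubiquitin-like modifier, DAZL (2.41 ± 0.13), TRIM36 (2.33 ± 0.09), the copper chaperone cox17 (2.26 ± 0.05) and cldng (2.25 ± 0.11). Among the largest average falls were those of krt5 (-3.09 ± 0.17), CRABP2 (-2.87 ± 0.08), krt92 (-2.79 ± 0.15) and afp4 (-2.71 ± 0.20). Of 81 ribosomal protein genes 76 fell on average (camera adjusted p = 2.86e-16, and adjusted p = 0.266 with an estimated correlation), and 15 of 16 germ plasm genes rose (adjusted p = 1.86e-05, and adjusted p = 0.0916 with an estimated correlation). Limma called 12501 genes (6861 up, 5640 down; 5396 up and 7204 down of 12600 after rescaling). The test of whether the change from 2.5 to 6 hpf itself differed called 12926 genes (8902 up, 4024 down; 5502 up and 6854 down of 12356 after rescaling), with the median of all genes at 0.60. Its extremes were her5 (5.46 ± 0.18), ccnp (5.41 ± 0.19), the glycogen synthase GYS1 (5.23 ± 0.24), BTG4 (5.21 ± 0.32) and arpp21 (5.17 ± 0.26) upward. Downward they were fetub (-7.61 ± 0.30), eve1 (-6.72 ± 0.29), HKDC1 (-6.63 ± 0.25), afp4 (-6.49 ± 0.26) and apoa1b (-6.46 ± 0.29). Camera called 13 lists for the average and 14 for the interaction, and 0 of either with an estimated correlation.

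Genes were also sorted by their course over time, averaged over both injections, to ask how far morphants had gone along it. The 4040 declining genes, which include 21 of 33 oocyte and egg genes, had medians of -0.12, 0.30 and 1.64 in morphants relative to controls at 2.5, 4 and 6 hpf. At 6 hpf 3473 of them were higher and 169 lower (camera p = 2.6e-32, and p = 0.00265 with an estimated correlation). The 2231 rising genes, which include 30 of 47 early zygotic genes, had medians of 0, -0.52 and -1.37. At 6 hpf 1576 of them were lower and 299 higher (camera p = 2.98e-30, and p = 7.33e-05 with an estimated correlation). Averaged over the times, the mean difference of the declining class was 0.59 (exact permutation p = 0.0648) and that of the rising class -0.65 (exact permutation p = 0.00926, the smallest the arrangements can give). In controls declining genes changed by a mean of -2.73 from 2.5 to 6 hpf and in morphants by -0.98. That is 35.8% of the control change (33.2 to 38.6% over 16 combinations of single libraries). Rising genes reached 61.3% (60.8 to 61.8%), although rescaling brought the classes to 51.7% and 49.3%. On a straight line between the control times, morphants at 6 hpf matched controls at 4.48 hpf (4.43 to 4.53) by declining genes and 4.42 hpf (4.39 to 4.46) by rising genes. Morphants at 4 hpf matched 3.22 hpf (3.16 to 3.28) by declining genes and 3.42 hpf (3.37 to 3.46) by rising genes. These ranges, on unscaled TPM, do not overlap. The hour matched at 4 hpf was not computed after rescaling. Rescaling brought the shares of the control change from 2.5 to 4 hpf close together in the 2 classes. Whether the classes match different hours at 4 hpf therefore cannot be told apart from the scaling.

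**Figure D3:**
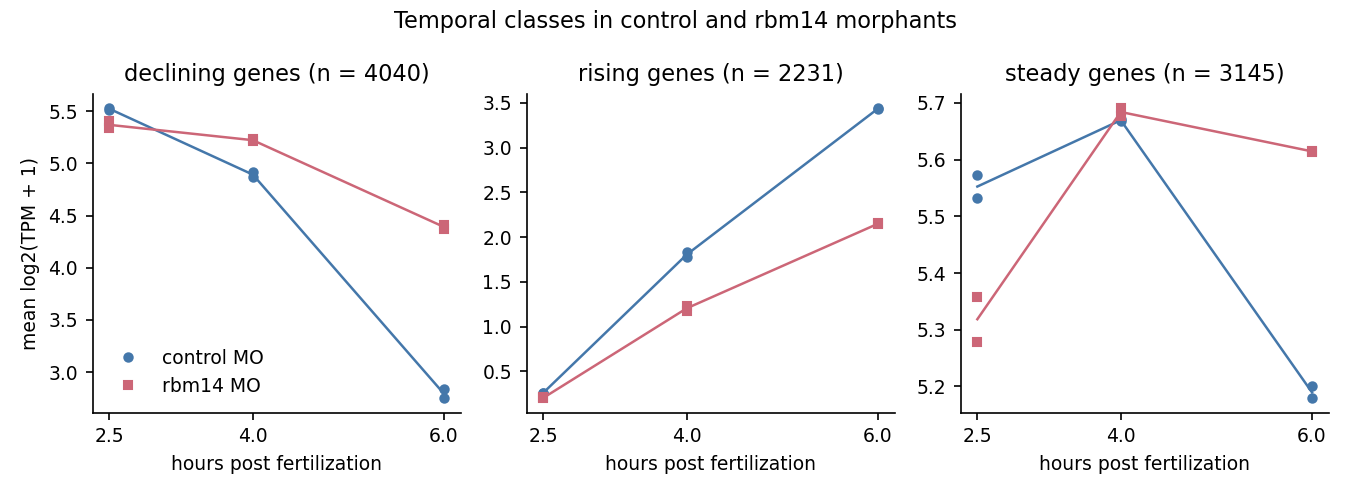
Mean log2(TPM + 1) of the declining, rising and steady (little changed over time) classes in each zebrafish library against hours post fertilisation, for control and rbm14 morpholinos. From 2.5 to 6 hpf morphants covered 35.8% of the control change in declining genes and 61.3% in rising genes.

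In mouse blastocysts the question was which genes differ in embryos labelled ko, and no single gene passed the test. The 5 genes nearest to a rise were Fam25c (3.60 ± 0.96), Rasl10a (2.76 ± 0.76), the lysosomal protease Ctsz (2.51 ± 0.71), Ubl4 (1.36 ± 0.39) and Pdlim4 (2.30 ± 0.70), each with limma adjusted p = 0.761. Those nearest to a fall were the histone variant H2afx (-1.19 ± 0.25), the fatty acid desaturase Fads2 (-2.06 ± 0.44), Trim43a (-1.31 ± 0.30), the cyclin-dependent kinase cofactor Cks2 (-0.96 ± 0.25) and the carnitine carrier Slc25a20 (-1.11 ± 0.31), with the same adjusted p. Heat shock genes, as a mean over 16 genes per embryo, were higher in 6 of 6 ko embryos than in any control, by 0.88 between the groups (exact permutation p = 0.0119, adjusted p = 0.25). The lowest ko embryo (6.97) and control 10 (6.97) were almost equal, and control 5 stood at 4.86. Without control 5 the heat shock difference was 0.19 (exact permutation p = 0.0714). Nuclear oxidative phosphorylation genes were higher in 5 of 6 ko embryos, by 0.22 (exact permutation p = 0.0357, adjusted p = 0.375), and by 0.12 without control 5 (exact permutation p = 0.143). The p53 response list was called downward by camera (median -0.62; adjusted p = 2.03e-05, and adjusted p = 0.995 with an estimated correlation). Its members with the smallest p were Gdf15 at -2.55 ± 1.05, the cell cycle inhibitor Cdkn1a at -1.13 ± 0.47, Pmaip1 at -1.45 ± 0.76 and Plk3 going the other way (2.41 ± 1.11). Without control 5, ko 8 and ko 9 its median was -0.09 (adjusted p = 0.442). Lineage lists were not called, with camera adjusted p = 0.935 for naive and epiblast genes and 0.514 for both primitive endoderm and trophectoderm genes.

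Sex ran along with the mouse groups. Xist, which is transcribed from the inactive X chromosome, stood at 0.678 TPM in control 2 and 0.212 TPM in control 5 but at 47.6 TPM in control 10 and 21.5 to 66.9 TPM in the ko embryos. The Y-linked gene Eif2s3y stood at 119.5 and 71.1 TPM in controls 2 and 5, at 1.40 TPM in ko 3, and had no fragment in the other 6 embryos. Without control 10 limma called 3 genes, which were named after their values were seen: Xist (4.91), Eif2s3y (-6.33) and the X-linked homeobox gene Rhox5 (6.05), which control 10 expressed at 398.5 TPM. With all 9 embryos limma-trend called 0 of 11781 genes, with 344 genes at an unadjusted p under 0.05 where chance gives 589. The count was 0 with limma-voom, 0 with a term for Y-linked expression, and 18 with embryo weights (9 up, 9 down). The median of all genes lay 0.30 higher in ko embryos, but at -0.13 without control 5 and at 0.61 without control 2. Camera called 1 list with all embryos, 7 without control 5, 3 without ko 7 and 2 without control 2, ko 4 or ko 8.

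**Figure D4:**
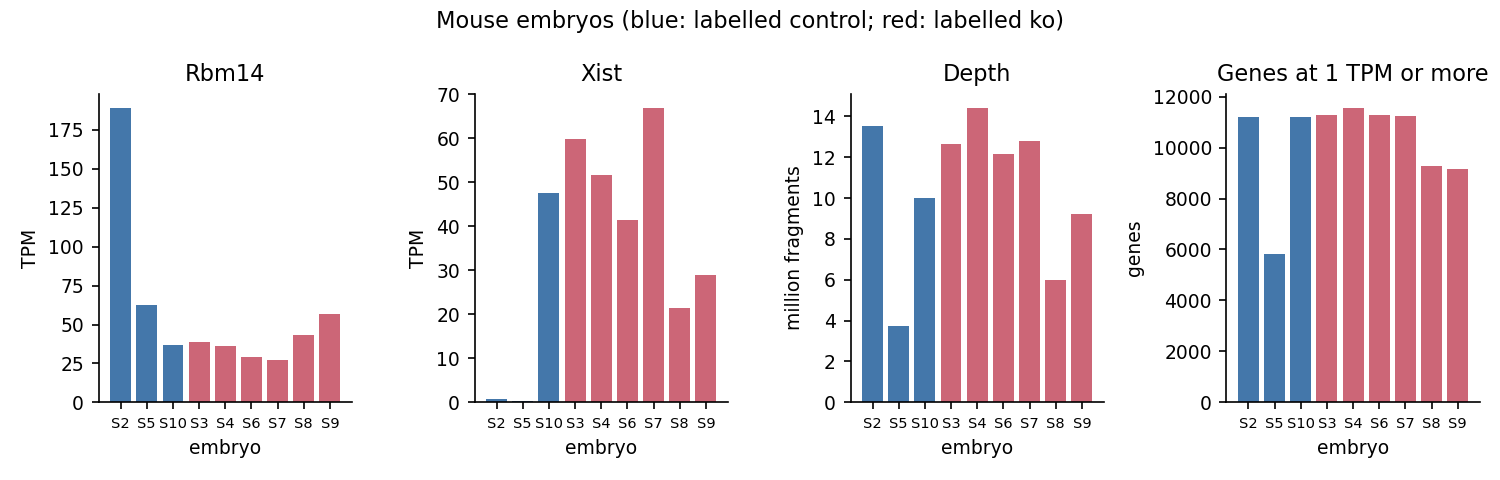
TPM of Rbm14 and Xist, depth in fragments and number of genes at 1 TPM or more in each mouse embryo, by the group in its label. Control 10 had Rbm14 at 36.6 TPM and Xist at 47.6 TPM, both within the range of the ko embryos.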

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

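The tests of a wrong time label, of the early difference at 2.5 hpf and of the library labelled control 10, and the rescaled counts of opposite differences, were chosen after the results were seen; those of a delay, of scaling at 6 hpf and of other splits were fixed before.

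The change over time differed between injections at 12926 genes from 2.5 to 6 hpf, 4089 from 2.5 to 4 hpf and 11628 from 4 to 6 hpf by limma's interaction test. After rescaling the interval from 2.5 to 4 hpf had 2644 calls, 964 of them rises, against 2929 rises among the 4089. Among genes with a called difference between the times, 1840 were lower in morphants at 2.5 hpf and higher at 6 hpf and 179 were the reverse, but 576 and 724 after rescaling, so this imbalance depends on the scaling. Paraspeckle and related proteins, such as EWSR1, had a median difference between the times of -0.73 (-1.62 after rescaling), and ribosomal protein genes of -1.46 (-2.38). In mouse, ko 8 had the lowest mean of nuclear oxidative phosphorylation genes among ko embryos, 8.40, far from the other 5, and ko 7 the lowest Ctsz, 56.4 TPM. Of 31 groups tested for such distant samples 2 had one, and chance gives about 1 in 20.

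By the means of declining and rising genes, morphants at 6 hpf lay between the controls of 4 and 6 hpf, as nanog did, while CCNA1 lay above both. A delay of development and nothing else would keep genes that rise or fall at both control steps within the control range of 2.5 to 6 hpf. Of 5092 such genes 3.77% (192) lay outside it (4.31% after rescaling, tried after the results were seen), under the 5% set as the bound, and 4423 fell short of the 6 hpf control level. Of wrong time labels on the morphant 6 hpf libraries, the 9214 genes called between morphants of 6 and 4 hpf argue only against 4 hpf. They cannot speak on collection or staging at another earlier hour. The scaling of TPM is argued against by class medians of 1.08 and -1.97 after rescaling. The 5% bound is also met where a change is only slowed or partial, so it does not single out a delay. A delay may account for the course of most of the 5092 genes. A specific loss of mRNA clearance, which the design also allows, was not separated from it. Of all 17920 genes tested, 1610 lay above and 1481 below both controls of 4 and 6 hpf (1623 and 1812 after rescaling). That comparison was chosen after the results were seen. For the average difference 2 of 100 splits within times, the real one (12501 genes) included, called as many, under the 5% set as the bound. The other (12767 genes) exchanged the labels at 2.5 hpf alone. All splits that kept the 6 hpf labels called 6303 genes or more and all others 0, so the count rests on the grouping at 6 hpf and does not speak for 2.5 or 4 hpf. With 2 libraries per group at 6 hpf few groupings exist, so the splits cannot exclude chance.

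Morphants and controls already differed at 2.5 hpf, at genes such as fthl27, ITM2C and the mitochondrial MT-CO1. A few abundant mitochondrial transcripts taking more of the total is argued against, since 95.6% of the genes called were still called in the same direction without them. Embryos of other parents in the morphant pools could leave such differences. Among genes steady over time the differences at 2.5 hpf correlated with those at 4 hpf at r = 0.53 but with those at 6 hpf at r = 0.062, across genes that are not independent. Parents and morpholino cannot be told apart, since the labels give no clutches. Whether most genes truly fell cannot be told apart from the scaling either, because rescaling centres the genes and by construction brings the share of rises to 49.3%. That share met the bound set for the scaling, and the test was judged uninformative only afterwards.

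The embryo labelled control 10 had Rbm14 at 36.6 TPM, within the range of the ko embryos. A mislabelled sample would lie there, but this restates the pattern and decides nothing, so a wrong label cannot be told apart from other causes of a low level. The sex of the embryos stays open, since both controls with low Xist had more Rbm14 (62.7 TPM in the lower) than all 6 ko embryos, and no control with high Xist other than this one exists, so that sex and genotype cannot be told apart. Heterozygous controls, which the cross would yield, were not told from wild type in the labels. For the mouse comparison other splits decide nothing about chance, since the real one called 0 genes and all 84 splits call at least as many by construction. The highest other split called 996 genes. It set control 5, ko 8 and ko 9 apart, the 3 libraries with the fewest fragments and the fewest genes at 1 TPM, which points to a structure of the samples, and depth was not separated from the quality of embryo or amplification.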

How the results depend on the processing

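Limma-voom, the fits without the 3 shallow mouse libraries, the alternatives for the matched control hour, the classes with an estimated correlation, the rescaled counts of genes outside control levels, of opposite differences and of the interaction per interval, and the leave-one-out values of lists, classes, shares and list means were chosen after seeing the data; the others were fixed before. Of 11727 values of named genes under alternatives, 11605 kept direction and side of the threshold, 95 lost it, 17 gained it and 10 reversed; of 2959 values of lists 2743 were kept, and of 607 of counts, classes and shares 539. Reversals count called results only. Limma-voom called 4584, 5673 and 14036 genes at 2.5, 4 and 6 hpf. Unless a reason is given, the cause was not tested.

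At 2.5 hpf the count of 4430 became 2836 with quantile normalization (1263 up, 1573 down), 2830 with limma arrayWeights, 2070 of 14113 genes tested with only the 4 libraries compared, and 2842 to 4769 without single libraries. At 4 hpf the count of 5755 became 7383 with limma arrayWeights, 7080 of 15735 with only the 4 libraries compared, and 3576 to 6687 without single libraries. The mouse count was 18 with arrayWeights and 0 to 3 without single embryos. In zebrafish a left-out library leaves 1 in its group, assumed to vary like the others. With an estimated correlation camera called 0 lists at 2.5 hpf, 4 hpf, 6 hpf, for the average, the interaction and the mouse, 1 for control 4 against 2.5 hpf and 5 for control 6 against 4 hpf. Fry called 21 for the average and 0 for the mouse. In the mouse camera called 4 without the 3 shallow libraries and 1 to 7 without single embryos.

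The declining class at 2.5 hpf had a median of -0.067 (camera p = 0.034) with 4-fold classes and 0.094 (p = 0.00446) after rescaling, which also gave the mean over the times as 0.52 (exact permutation p = 0.00926). Rescaling took the rising class at 2.5 hpf to 0 with the other sign in camera (p = 0.604), and the steady class to 0.055 at 6 hpf (p = 0.0341) and 0.022 over the times (exact permutation p = 0.0463). The steady class at 2.5 hpf ranged from -0.26 to -0.14 without single libraries. Shares of the control change for 2.5 to 4, 4 to 6 and 2.5 to 6 hpf were 44.2, 45.5 and 45.1% for declining genes with 4-fold classes and 66, 45.2 and 51.7% after rescaling, and for 4 to 6 and 2.5 to 6 hpf 36.1 and 32.6% with pseudocount 0.1. For rising genes they were 72.6, 67.2 and 70.16% with pseudocount 0.1 and 60.8, 42.4 and 49.3% after rescaling, and 65.2% in both later intervals with 4-fold classes. Without single libraries they ranged from 21.8 to 29.2% (declining, 2.5 to 4 hpf), 56.3 to 73.2% (rising, 4 to 6 hpf) and 61.1 to 68.8% (rising, 2.5 to 6 hpf). The control hour matched at 6 hpf by declining and rising genes was 4.55 and 4.47 with 4-fold classes, 4.44 and 4.5 with pseudocount 0.1, and 4.52 and 4.35 after rescaling, and for rising genes 4.40 to 4.52 without single libraries.

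Rescaling reversed rbm14a at 6 hpf (-0.27) and in the interaction (-0.35; -0.022 with quantile normalization), and MT-ND4 (-0.033), MT-ND5 (-0.024), MT-ND1 (-0.013), mt-nd4l (-0.061) and the mitochondrial genome list (-0.21) at 6 hpf. Genes lower at 2.5 hpf and higher at 6 hpf numbered 576 after rescaling and the reverse 724, and the interaction from 2.5 to 4 hpf called 2644. Genes above both later control times numbered 0 of 13 in the mitochondrial genome list after rescaling. Quantile normalization reversed MT-CO1 (-0.53), MT-CYB (-0.41) and MT-CO3 (-0.44) between control 4 and 6 hpf. Fry gave the other direction for the mitotic list at 2.5 hpf (median 0.033) and the oxidative phosphorylation list in the interaction (median -0.088).

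Replicate numbers in the labels showed no pairing of libraries at 4 or 6 hpf or across times. Deviations from group means correlated there at -0.061 to 0.058 between groups. Between both groups of 2.5 hpf they correlated at 0.293, so a pairing at that time stays open. The replicate block is a single term shared by all 6 groups, so it cannot test a pairing at 2.5 hpf only. With a replicate block limma called 4404, 5738 and 14031 genes at 2.5, 4 and 6 hpf, 12559 for the average and 12950 for the interaction, and camera called 6, 12 and 13 lists at the 3 times, the 6 hpf calls of cholesterol (adjusted p = 0.051) and mitochondrial genome genes (0.0533) ending. With 3720585 to 14403449 fragments per mouse embryo and 3 controls, simulated changes of 1.5-fold and 2-fold were not recovered in mouse.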

Other observations

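The p53 test and the comparison of morphants at 6 hpf with both later control times were chosen after the results were seen. Of 24 p53 response genes, 12 lay above both control times of 4 and 6 hpf and 2 below both, against 1610 of 17920 genes (9%) above both. After rescaling 9 of the 24 lay above both, against 1623 of all genes (9.1%). The p53 inhibitor mdm2 stood at 298 TPM, against 120.3 at 4 hpf and 113 at 6 hpf in controls, and the cell death gene bbc3 at 58.5 against 25.8 and 4.05 TPM. GADD45A (ENSDARG00000043581) stood at 145 against 43.6 and 9.38 TPM, and PHLDA3 at 139.7 against 55.2 and 24.5 TPM. Against controls of 4 hpf the list was called upward by camera (adjusted p = 3.74e-06, and adjusted p = 0.252 with an estimated correlation); at 6 hpf itself it had 16 rises and 5 falls (adjusted p = 0.177), and its median of 0.81 became 0.16 after rescaling. Of 16 germ plasm genes 7 lay above both with either scaling, while all 13 mitochondrial genome genes did so in TPM and 0 after rescaling.

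Stress and cell cycle genes split. At 6 hpf the endoplasmic reticulum chaperones HYOU1 (3.41 ± 0.07), HSP90B1 (2.40 ± 0.08) and HSPA5 (1.78 ± 0.06) were higher. Controls reduced all 3 between 4 and 6 hpf. HSPB1 was lower (-3.05 ± 0.13), and 8 members of the heat shock and unfolded protein list rose and 16 fell (camera adjusted p = 0.0129, and adjusted p = 0.129 with an estimated correlation). Among 52 mitotic genes 19 rose and 24 fell (adjusted p = 0.0537, and adjusted p = 0.28 with an estimated correlation), with CCNA2 (1.46 ± 0.06) and CDK1 (-1.88 ± 0.12) on opposite sides. After rescaling that list was called downward at the preset correlation (median -0.78, adjusted p = 0.0015). Of 22 centriole assembly genes 14 rose and 4 fell (adjusted p = 0.247), among them poc1b (1.97 ± 0.09) and CEP97 (1.72 ± 0.11), although the list's median turned from 0.56 to -0.04 after rescaling. Interferon genes had 8 rises and 5 falls among 14 (adjusted p = 0.968), and maternal mRNA stabilising and translation factors 10 rises and 14 falls among 26 (adjusted p = 0.0573, and adjusted p = 0.214 with an estimated correlation). After rescaling the latter list was called downward at the preset correlation (median -1.10, adjusted p = 0.0114). In mouse, genes of the 2-cell stage were high in ko 8 (5.85 as a mean log2 level) and control 10 (5.29) against 2.44 to 3.86 in the other embryos.

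The share of p53 genes above both later control times, 50% (37.5% after rescaling), is the pattern itself and tests no cause. A morpholino effect that is not specific to rbm14 and a p53 response to the loss of Rbm14 cannot be told apart, since no rescue or mutant is among the zebrafish libraries.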
